A study of Mus musculus with 10 samples.

How the data were processed

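Total RNA from lung tissue of wild-type mice was extracted with Trizol and made into Illumina libraries, per the labels. The deposited table holds raw read counts per gene for 10 libraries, which the authors made with CASAVA, HISAT2 and HTSeq 0.6.0 on the mouse build GRCm38/mm10. The annotation release, the strand setting, doses and time points are not stated. The values were checked to be whole numbers, with totals per library from 16175172 to 18374461. The table has 54532 genes named by Ensembl identifiers, of which 31040 had at least 1 count, and 54495 (99.93%) were in the reference annotation. It gave positions, biotypes, GC content and length. Symbols that a spreadsheet had turned into dates (27) were restored by identifier. No library was a copy of another of its group, by a chi-square comparison of each pair within a group. Libraries of different groups were not compared in this way.

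Libraries were grouped by the treatment given in the labels: Vehicle (3), LPS (3) and LPS+TSLP (4). The 3 comparisons were LPS against Vehicle, LPS+TSLP against LPS and LPS+TSLP against Vehicle. Counts were filtered with filterByExpr, which kept 17139 genes, scaled by TMM and tested by edgeR 4.0.16 quasi-likelihood (robust) in R 4.3.3, with all 10 libraries in 1 fit of 3 groups and 7 residual degrees of freedom. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, two-sided. Log2 fold changes, their standard errors and adjusted p-values are from that fit, and log2 CPM values used a prior count of 2. Libraries with equal replicate numbers had correlations from −0.34 to 0.4 after group means were removed, over 0.1 in 3 pairs, so the numbers were not taken as a pairing and no block was used. Simulations with no effect (20) gave the correlation that comes from the shared Vehicle libraries. No library was left out of the tests reported first.

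Gene lists for pathways, lung and immune cell types and other tissues (38) were fixed before the data were examined, as were the comparisons, tests, first alternatives and the rule for naming genes. Lists with at least 5 tested members (37) were tested by camera of limma 3.58.1 with its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. Beside each call stand camera with an estimated correlation and the number of members called over all genes and adjusted over the list alone. The list of sex-linked control genes had too few tested members, and values are given for Xist and the Y-linked genes. Exact permutation tests of list means and of the response score enumerated all splits of the libraries, 35 for LPS+TSLP against LPS and 10 for LPS against Vehicle, where the smallest possible p is 0.1.

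The rule for naming genes took, per comparison, the 8 protein-coding genes with the largest and the 8 with the smallest log2 fold change among those called, with at least 1 CPM in the higher group and no overlap between groups. It added all 30 anchor genes, and up to 4 members with the smallest adjusted p from every other list. The text names the first genes in that order. How many to name, and which lists to illustrate, was settled after the values were seen. Anchor genes left unnamed did not pass in LPS against Vehicle (9 genes) or LPS+TSLP against LPS (11 genes). Of these, 3 and 7 changed sign under at least 1 alternative. In LPS+TSLP against Vehicle 25 anchor genes are unnamed, none passed, and 12 of them changed sign. Il1b, Tnf and Cxcl2 were added there after their values were seen, because they open the account of LPS.

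Reads shared between genes were gauged as the share of 50-base stretches of a gene's transcripts, sampled 1 in 8, that also occur in another annotated gene. A trend of each library's log2 counts with GC content or gene length was fitted by loess (span 0.3) and removed with offsets as an alternative. Other alternatives were DESeq2 1.42.0 size factors, upper quartile factors, library size alone, no filter, a filter of 1 CPM in at least 3 libraries, the DESeq2 Wald test, limma-voom, fits of the groups compared alone, the replicate number as a block, removal of haemoglobin, mitochondrial and immunoglobulin genes, stricter thresholds, fry, and leaving out each library in turn. For genes with 1 to 3 counts in a group, 95% counting intervals of the ratio are given, and a group with 0 counts was compared with a floor of 3 counts over the group.

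The tests were run on simulated data of the same size and spread. Of spiked changes of 2-, 4- and 8-fold, 8.96%, 62.7% and 90.9% were found for LPS against Vehicle, 10.4%, 71.6% and 84.8% for LPS+TSLP against LPS, and 20.9%, 64.2% and 83.3% for LPS+TSLP against Vehicle, with 3, 6 and 4 false calls. Only 67, 67 and 66 genes of 17139 were changed by these folds, whereas 4273 genes were called in LPS against Vehicle. The adjusted threshold depends on how many genes change, so the shares found do not describe comparisons with many calls. The response score, given a simulated share of 0.6 of the LPS response, returned a mean of 0.564 in the LPS+TSLP libraries. A simulated GC trend made 890 false calls before its removal and 27 after.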

Results

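RNA sequencing of whole lung tissue from wild-type mice covered 10 libraries in 3 groups. Vehicle held 3 libraries and LPS held 3, lipopolysaccharide being a bacterial outer-membrane component that activates innate immunity through the receptor TLR4. The remaining 4 libraries (LPS+TSLP) came from lungs given recombinant TSLP before LPS. TSLP, thymic stromal lymphopoietin, is an epithelial cytokine that signals through a receptor made of CRLF2 and IL7R. Total counts per library were 17505995, 18374461 and 17631643 in Vehicle replicates 1 to 3, 17860592, 17570784 and 18062922 in LPS replicates 1 to 3, and 16175172, 17136287, 18003507 and 16448334 in LPS+TSLP replicates 1 to 4. Between 20623 and 23917 genes had at least 1 count in a library, and 17139 genes were tested. Levels below are CPM given as mean ± SD, and genome positions are those of GRCm38/mm10.

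LPS+TSLP replicate 1 stood apart from the other libraries. Mitochondrial genes took 13.1% of its counts, against 6.50%, 5.35% and 2% in LPS+TSLP replicates 2 to 4, 1.2% to 2.58% in LPS and 1.11% to 1.27% in Vehicle. It lay at −101 on the second principal component (20.2% of the variance), where the other 9 libraries lay between −39.1 and 34.3. On the first component (43.4%) the Vehicle libraries lay between −103 and −53 and the LPS libraries between 35.2 and 61.8. LPS replicate 1 differed in sex-linked genes: it had 206 CPM of Xist, the X-inactivation RNA, where no other library passed 0.452 CPM, and 0 CPM of the Y-linked gene Ddx3y, where the others had 6.03 to 94.8 CPM. No label says that the libraries of a group come from separate animals, so the p-values below measure the spread between these samples.

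LPS against Vehicle asked what LPS changed in the lung. Cxcl2, a neutrophil attractant (ENSMUSG00000058427, chromosome 5, 90903871 to 90905938), reached 536 ± 190 CPM after LPS (n = 3) against 14.7 ± 21.8 CPM in Vehicle (n = 3), a log2 fold change of 5.19 (SE 1.4, adjusted p = 0.022). Tnf, a central inflammatory cytokine (ENSMUSG00000024401, chromosome 17, 35199381 to 35202007), went from 9.35 ± 9.76 to 104 ± 40.6 CPM, a log2 fold change of 3.47 (SE 0.79, adjusted p = 0.012). Il1b, which drives fever and leukocyte recruitment (ENSMUSG00000027398, chromosome 2, 129364570 to 129371139), went from 72.6 ± 63 to 448 ± 207 CPM, a log2 fold change of 2.63 (SE 0.72, adjusted p = 0.024). In these 3 genes all 3 LPS libraries lay above all 3 Vehicle libraries, and without Vehicle replicate 3 the values were 7.98, 4.74 and 3.54. Collagen XIV (Col14a1, ENSMUSG00000022371, chromosome 15, 55307750 to 55520803), a fibroblast matrix gene, fell from 79.5 ± 37.9 to 4.40 ± 2.07 CPM, a log2 fold change of −4.17 (SE 0.54, adjusted p = 0.002).

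**Figure D1:**
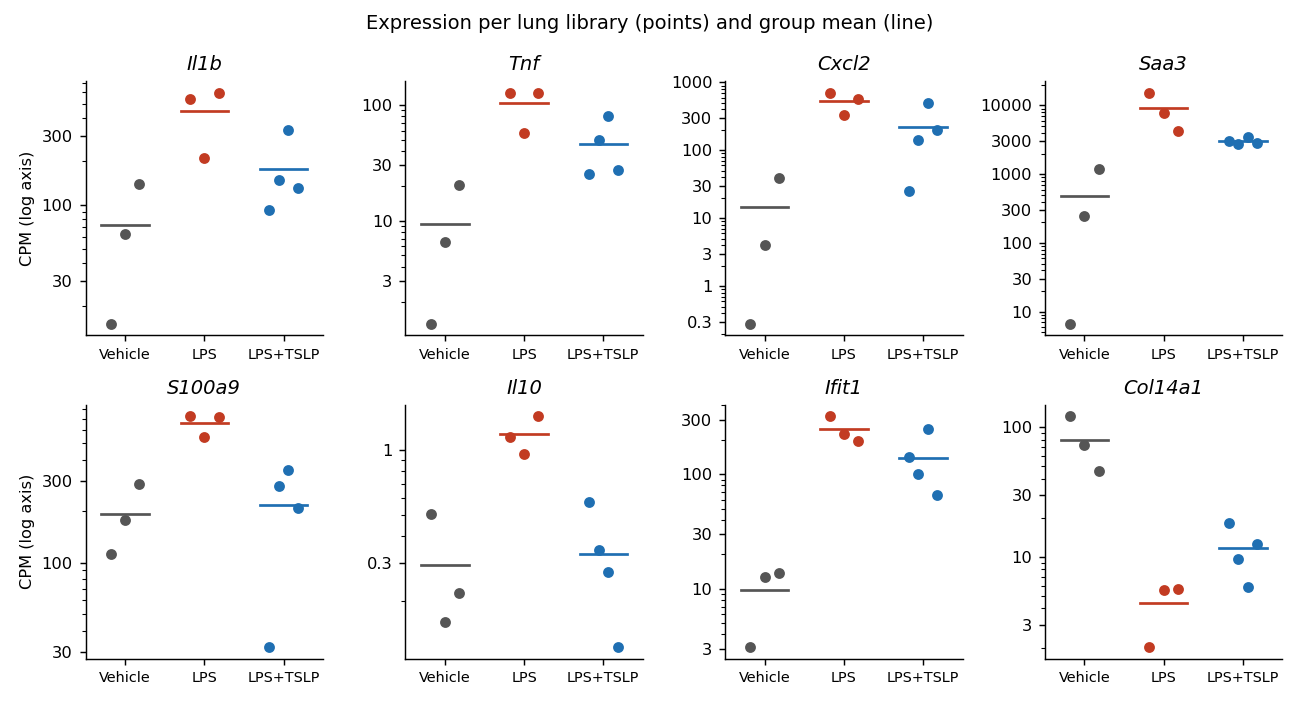
Levels of 8 genes per lung library in CPM on a log axis, by group, with points for libraries and lines for group means. Il1b, Tnf, Cxcl2, Saa3, Il10 and Ifit1 passed the test as higher and Col14a1 as lower in LPS than in Vehicle, S100a9 did not pass (adjusted p = 0.063), and none of the 8 passed between LPS+TSLP and LPS.

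Among 32 tested inflammatory cytokines and chemokines, 20 rose, 1 fell and 11 did not pass the test after LPS (25 rose and 2 fell adjusted over the list alone), with a median log2 fold change of 2.47. The mean log2 CPM of the list was 1.73, 3.29 and 4.12 in Vehicle replicates 1 to 3, so the Vehicle libraries differed widely. The macrophage inflammatory chemokines Ccl3 and Ccl4 rose by log2 4.96 (SE 1.1, adjusted p = 0.011) and 4.48 (SE 0.77, adjusted p = 0.0042), and by 7.03 and 5.57 without Vehicle replicate 3. Among 25 NF-kB feedback and response genes, 18 rose and 7 did not pass (20 adjusted over the list alone), with a median of 1.35. Tnip3 and Nfkbia, inhibitors of NF-kB signalling, rose by 2.82 (SE 0.40) and 1.95 (SE 0.31). Interferon-stimulated genes numbered 47, of which 19 rose and 28 did not pass (32 adjusted over the list alone), with a median of 1.44. Gbp7, a guanylate-binding protein of cell-autonomous defence, went from 17.8 ± 8.72 to 303 ± 71.9 CPM (log2 4.09, SE 0.46, adjusted p = 0.0016). Ifit1, an antiviral RNA-binding protein, went from 9.82 ± 5.84 to 247 ± 66.4 CPM (log2 4.65, SE 0.62, adjusted p = 0.002). Camera with its preset correlation called each of these 3 lists higher (adjusted p from 1.81e-11 to 4.37e-09), and each had an adjusted p = 0.611 with an estimated correlation.

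Of 32 neutrophil markers, 13 rose and 19 did not pass (18 adjusted over the list alone), with a median of 1.78. Trem3, a myeloid surface receptor, rose by 2.16 (SE 0.39, adjusted p = 0.0052). Itgam, the integrin CD11b, rose by 2.77 (SE 0.41, adjusted p = 0.0026), although a share of 0.654 of its 50-base stretches also occurs in another annotated gene, so its level is uncertain. Inflammasome and cell death genes had 12 risen among 28 (15 adjusted over the list alone), with a median of 0.93. They included Casp4, the sensor of intracellular LPS (log2 2.74, SE 0.43), and the DNA sensor Aim2 (1.74, SE 0.28). MHC class I and immunoproteasome genes had 12 risen among 19 (17 adjusted over the list alone), with a median of 1.09, and the proteasome activator subunit Psme2 rose by 2.72 (SE 0.50; 2.11 without LPS replicate 1). Among 30 monocyte and interstitial macrophage markers 8 rose (11 adjusted over the list alone), with a median of 0.83. These 4 lists were called higher by camera (adjusted p from 5.26e-06 to 0.00245), with adjusted p = 0.611 with an estimated correlation for each.

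Stromal lists were lower. Among 32 fibroblast and matrix genes 11 fell, 2 rose and 19 did not pass (17 fell and 2 rose adjusted over the list alone), with a median of −0.92. Beside Col14a1, the peptidase inhibitor Pi16 of adventitial fibroblasts fell from 61.5 ± 6.01 to 17.5 ± 0.987 CPM (log2 −1.81, SE 0.31, adjusted p = 0.004). Smooth muscle and pericyte markers had 10 fallen, 1 risen and 11 not passing among 22 (13 fallen and 1 risen adjusted over the list alone), with a median of −0.95. Notch3, a receptor of mural cells, fell by 1.94 on the log2 scale (SE 0.34) and the smooth muscle myosin Myh11 by 1.81 on the log2 scale (SE 0.34). Camera called both lists lower (adjusted p = 6.08e-06 and 6.34e-05), each with adjusted p = 0.611 with an estimated correlation. Of 30 alveolar type 2 markers 8 fell, 1 rose and 21 did not pass (8 fell and 2 rose adjusted over the list alone), with a median of −0.57 (camera adjusted p = 0.045, adjusted p = 0.775 with an estimated correlation). With the GC trend removed that call was lost (median −0.53, camera adjusted p = 0.0621). Lgi3 fell by 2.07 on the log2 scale (SE 0.47), whereas Lamp3, a lysosomal protein also made by mature dendritic cells, rose by 2.61 (SE 0.54, adjusted p = 0.0082) and no longer passed once each library's trend with GC content was removed (1.17, adjusted p = 0.058).

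Mitochondrially encoded mRNAs had 4 risen among 13 (4 adjusted over the list alone), with a median of 1.14. Their camera call (adjusted p = 0.0139) had adjusted p = 0.66 with an estimated correlation, and after removal of the GC trend 0 passed and the median was −0.70. mt-Nd6, a subunit of respiratory complex I, rose by 2.30 (SE 0.38, adjusted p = 0.0037), and with the GC trend removed its log2 fold change was 0.06 (adjusted p = 0.95). Camera called 12 further lists at its preset correlation, none of which passed with an estimated correlation (adjusted p between 0.611 and 0.776). Higher were acute phase and antimicrobial proteins (7 of 30 rose; median 0.55), NK cell and cytotoxic genes (4 of 25; 0.70), and STAT5 and cytokine receptor target genes (6 rose and 2 fell of 21; 0.585). Called higher too were LPS receptor and TLR signalling genes (9 and 1 of 28; 0.71), coagulation and fibrinolysis genes (8 and 2 of 24; 0.66), arachidonic acid and nitric oxide genes (11 and 2 of 29; 0.48) and glucocorticoid-responsive genes (5 of 22; 0.89). It called lower the lists of B cell markers (5 fell and 1 rose of 24; −0.52), ciliated cell markers (3 and 1 of 33; −0.62), and fluid and ion transport genes (4 of 30; −0.42). The other lists called lower were cell cycle genes (6 and 2 of 36; −0.51), and skeletal muscle, thyroid, fat, thymus and squamous epithelium markers (1 of 12; −1.16). Adjusted over the list alone, the counts risen were 7, 1, 7, 14, 10, 12 and 5 for the higher lists in that order, and the counts fallen were 6, 3, 3, 9 and 0 for the lower ones. With the GC trend removed 4 of these 12 calls were lost: NK cell and cytotoxic genes (median 0.36, camera adjusted p = 0.171), coagulation and fibrinolysis genes (0.54, 0.0572), fluid and ion transport genes (−0.29, 0.0621), and skeletal muscle, thyroid, fat, thymus and squamous epithelium markers (−0.91, 0.0815). It added calls of immediate early genes (8 rose; median 0.54, camera adjusted p = 0.00129) and antioxidant and hypoxia genes (0.0457) as higher and of endothelial markers (0.0457) as lower. Before that removal camera with an estimated correlation gave these lists adjusted p = 0.66, 0.66 and 0.735. The other 14 lists were not called, among them type 2 immunity and TSLP-associated genes (4 rose and 1 fell of 29; camera adjusted p = 0.884).

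Of 30 anchor genes fixed in advance, 12 rose and 18 did not pass. Besides Cxcl2, Tnf and Il1b, the ones that rose were Saa3, an acute phase protein (481 ± 623 to 9130 ± 5720 CPM; log2 4.25, SE 1.2), the granulocyte growth factor Csf3 (3.84, SE 1.1), and the prostaglandin synthase Ptgs2 (3.53, SE 0.66). Rises were also found for the neutrophil attractant Cxcl1 (2.54, SE 0.80), the monocyte attractant Ccl2 (2.40, SE 0.80), the LPS co-receptor Cd14 (2.22, SE 0.56), the inducible nitric oxide synthase Nos2 (2.11, SE 0.61), the TSLP receptor chain Il7r (2.02, SE 0.48) and the anti-inflammatory cytokine Il10 (1.99, SE 0.65). Their adjusted p ranged from 0.0056 (Ptgs2) to 0.048 (Ccl2). Without Vehicle replicate 3 the values were 6.18 for Saa3, 5.85 for Csf3, 3.74 for Cxcl1, 3.16 for Ccl2 and 2.82 for Cd14. Saa3 was at 3.63 without LPS replicate 1, Nos2 at 1.39 without LPS replicate 3 and Il10 at 2.61 without Vehicle replicate 1. Values of others in that list were Il6 2.61 (adjusted p = 0.063), Cxcl10 2.83 (adjusted p = 0.068), and Lcn2 2.46 (adjusted p = 0.055). Those of uncalled genes were also S100a8 1.86 (adjusted p = 0.069), S100a9 1.77 (adjusted p = 0.063), Icam1 0.34 (adjusted p = 0.62), Tlr4 1.14 (adjusted p = 0.078) and Crlf2, the other TSLP receptor chain, 0.61 (adjusted p = 0.079). Endogenous Tslp had 1.25 ± 0.851 CPM in Vehicle and 2.14 ± 1.33 CPM after LPS (log2 0.77, SE 0.69, adjusted p = 0.43), and its value was −0.49 with the GC trend removed.

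The largest fitted rises among protein-coding genes without overlap between the groups included Gm15056, the zinc finger gene Zfp991, and Cbln1, a secreted synaptic organiser. Gm15056 had 1 count in all Vehicle libraries together against 72 after LPS, a ratio of 75.8 (95% counting interval 13.2 to 3030), and Cbln1 had 3 against 113, a ratio of 39.6 (13.2 to 195). The fitted log2 values, 5.80 and 5.14, were 7.62 for Gm15056 without Vehicle replicate 2 and 5.99 for Cbln1 without Vehicle replicate 3. Zfp991 went from 0.202 ± 0.0686 to 9.28 ± 1.35 CPM (log2 5.48, SE 0.41, adjusted p = 0.00024), but a share of 0.845 of its 50-base stretches occurs in other annotated genes. The largest falls included Gsg1l, an AMPA receptor auxiliary subunit, with 322 counts in Vehicle and 2 after LPS (ratio 153, interval 42 to 1270). Vehicle replicate 1 held 252 of the 322 counts of Gsg1l, whose fitted log2 value of −7.04 was −5.38 without that library and −9.70 without LPS replicate 3. Others were Hes2, a transcriptional repressor (4.18 ± 3.08 to 0.0983 ± 0.0732 CPM; log2 −5.33, SE 0.82, adjusted p = 0.0029), and the secreted Wnt modulator Sfrp2 (6.14 ± 4.78 to 0.192 ± 0.142 CPM; log2 −4.95, SE 0.90, adjusted p = 0.0051). Hes2 was at −4.66 without Vehicle replicate 1 and −6.06 without LPS replicate 1, and Sfrp2 at −4.09 without Vehicle replicate 1 and −5.63 without LPS replicate 2. Counting intervals and floors cover counting error only.

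In all, 2437 genes rose and 1836 fell after LPS, of which 1845 and 1169 changed at least 2-fold, and 6788 genes had an unadjusted p under 0.05. The groups did not overlap in 49.8% of genes, where chance gives 10%. With the GC trend removed 1860 genes were higher and 1542 lower, of which 1485 and 1200 were called in the same direction before, and Ccl2, Cxcl1, Il10 and Il7r no longer passed. With no filter on low counts 11 of the 36 named calls were lost: Cxcl2, Tnf, Il1b, Ccl2, Ccl3, Cd14, Csf3, Cxcl1, Il10, Nos2 and Saa3. The replicate number as a block ended the calls of Ccl2 and Saa3, a fit of Vehicle and LPS alone those of Ccl2, Cxcl1 and Saa3, and removal of the length trend those of Ccl2, Cxcl1 and Il10. Of the 45 named genes, those not called at first gained calls under some settings. Among these settings, the DESeq2 Wald test gained 6, and limma-voom, that block and that fit gained 3 each. The DESeq2 Wald test and limma-voom lost 0. Ccl2 was also lost with upper quartile factors, as was Il10, and with library size as the only scaling. Without LPS replicate 1 and LPS+TSLP replicate 1 together, Ccl2, Csf3, Cxcl1, Il10, Il1b and Saa3 were lost. Without 1 library the counts fell to 1021 and 640 (Vehicle replicate 1), 1012 and 824 (Vehicle replicate 2), 1558 and 964 (LPS replicate 1) and, for lower genes, 1223 (LPS replicate 2). Of the named calls, leaving out 1 library ended those of Tnf (without Vehicle replicate 2), Cxcl2, Csf3 and Saa3 (without Vehicle replicate 2 or LPS replicate 1), Il1b and Nos2 (without Vehicle replicate 1 or 2 or LPS replicate 1 or 3), and Cd14 (without Vehicle replicate 1 or 2 or LPS replicate 1). It also ended those of Il7r (without Vehicle replicate 1 or 2) and Gm15056 (without Vehicle replicate 1). Cxcl1, Ccl2 and Il10 lost theirs in 5, 8 and 8 of 10 such fits, with values of these genes from 1.39 (Nos2) to 7.98 (Cxcl2). Of the 23 list calls 12 were lost without at least 1 library: acute phase, B cell, NK cell, STAT5, TLR signalling, alveolar type 2, ciliated cell, coagulation, fluid transport, arachidonic acid, cell cycle, and skeletal muscle with thyroid, fat, thymus and squamous epithelium. Medians over the 10 fits ran from 0.102 to 1.21 for acute phase, 0.56 to 1.42 for NK cell, and 0.557 to 1.19 for coagulation. They ran from −0.804 to −0.277 for B cell, −0.798 to −0.288 for ciliated cell, and −2.09 to −0.868 for the skeletal muscle list.

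LPS+TSLP against LPS asked what TSLP given beforehand changed in the LPS-treated lung. No single gene passed the test, and inflammatory lists as a whole lay lower with TSLP under camera's preset correlation only, since no list passed with an estimated correlation (smallest adjusted p = 0.291). Cxcl2 had 217 ± 202 CPM with TSLP (n = 4) against 536 ± 190 CPM with LPS alone (n = 3), a log2 fold change of −1.31 (SE 1.1, adjusted p = 0.79). Il1b had 176 ± 106 against 448 ± 207 CPM (−1.35, SE 0.63, adjusted p = 0.62), and Tnf had 45.8 ± 25.6 against 104 ± 40.6 CPM (−1.18, SE 0.67, adjusted p = 0.69). Il10 had 0.329 ± 0.189 against 1.19 ± 0.243 CPM (−1.84, SE 0.59, adjusted p = 0.59), with all 4 LPS+TSLP libraries below all 3 LPS libraries.

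Of the 32 inflammatory cytokines and chemokines, 31 had a log2 fold change below 0, with a median of −0.995, and 0 passed (0 adjusted over the list alone). Camera called the list lower (adjusted p = 1.22e-13), but its adjusted p = 0.291 with an estimated correlation. The mean log2 CPM of the list was 6.03, 5.30 and 5.86 in the LPS libraries and 4.05, 4.57, 5.35 and 4.47 in the LPS+TSLP libraries, a difference of −1.12 (exact permutation p = 0.0857, two-sided). Ccl6, a macrophage chemokine, had the smallest adjusted p of the list after Il10 (122 ± 34.2 against 196 ± 27.1 CPM; −0.68, SE 0.22, adjusted p = 0.59). Neutrophil markers had a median of −1.11 over 32 members, of which 28 lay below 0 (camera adjusted p = 1.8e-17, adjusted p = 0.291 with an estimated correlation, exact permutation p = 0.0857). Over all genes 0 of them passed, and adjusted over the list alone 4 fell: Wfdc21 (72.1 ± 26.4 to 17.8 ± 9.18 CPM; −2.02, SE 0.48), Mrgpra2a (−2.01, SE 0.50), Ly6g, the classical neutrophil surface marker (5.68 ± 1.84 to 1.79 ± 0.819 CPM; −1.66, SE 0.41), and Trem3 (−1.22, SE 0.35). Over all genes each had an adjusted p = 0.59, and a share of 0.882 of the 50-base stretches of Mrgpra2a occurs in other genes. The neutrophil list mean of LPS+TSLP replicate 1, the library with 13.1% mitochondrial counts, was 2.68, below the other 3 LPS+TSLP libraries (3.97 to 4.72).

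NF-kB feedback and response genes had a median of −0.53 over 25 members (camera adjusted p = 5.63e-10, adjusted p = 0.371 with an estimated correlation), with the antioxidant enzyme Sod2 at −1.04 (SE 0.32) and Tnfaip2 at −1.08 (SE 0.38). Interferon-stimulated genes had a median of −0.50 over 47 members (camera adjusted p = 1.59e-09, adjusted p = 0.501 with an estimated correlation), with Gbp7 at −1 (SE 0.37) and the interferon-inducible GTPase Ifi47 at −0.81 (SE 0.38). Their mean log2 CPM was 7.31, 7.32 and 7.10 in LPS and 7.33, 5.82, 7.30 and 5.68 in LPS+TSLP, so that LPS+TSLP replicates 1 and 3 were not below the LPS range (exact permutation p = 0.371). MHC class I and immunoproteasome genes all lay below 0, with a median of −0.53 over 19 members (camera adjusted p = 5.63e-10, adjusted p = 0.304 with an estimated correlation), among them the class I heavy chain H2-K1 at −0.64 (SE 0.24) and Psme2 at −1.10 (SE 0.44). Endothelial activation and adhesion genes had a median of −0.46 over 23 members (camera adjusted p = 3.94e-06, adjusted p = 0.304 with an estimated correlation), with the TNF receptor Tnfrsf1b at −1 (SE 0.31) and the chemokine-binding venular receptor Ackr1 at −1.80 (SE 0.59). None of these genes passed over all genes (adjusted p from 0.59 to 0.62), and 0 members of these 4 lists passed adjusted over the list alone. Exact permutation p was 0.0857 for the NF-kB list, 0.2 for MHC class I and 0.0857 for endothelial activation.

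Lists that lay higher with TSLP were led by mitochondrially encoded mRNAs, with a median of 1.70 over 13 members (camera adjusted p = 2.02e-18, adjusted p = 0.291 with an estimated correlation, exact permutation p = 0.0857). Over all genes 0 passed, and 13 rose adjusted over the list alone. mt-Nd4l, a complex I subunit, rose in that sense from 4.92 ± 2.68 to 32.4 ± 17.5 CPM (log2 2.71, SE 0.57, adjusted p over all genes = 0.59). The cytochrome oxidase subunit mt-Co2 rose likewise, from 40 ± 13.2 to 218 ± 158 CPM (log2 2.44, SE 0.55, adjusted p over all genes = 0.59). All 50-base stretches of both genes also occur in other annotated genes, so their levels are uncertain. Smooth muscle and pericyte markers had a median of 0.60 over 22 members (camera adjusted p = 7.44e-10, adjusted p = 0.291 with an estimated correlation; 0 passed adjusted over the list alone). Their mean log2 CPM was 5.07, 5.45 and 5.01 in LPS and 6.02, 5.55, 5.54 and 5.98 in LPS+TSLP, the 1 list of 37 with an exact permutation p of 0.0286, the smallest the design allows (adjusted over the lists p = 0.352). LPS+TSLP replicate 1, the highest of them, was also highest in club and secretory cell markers (8.48, the other 3 between 5.32 and 5.97), ciliated cell markers (5.11, the others between 2.93 and 3.77) and heart muscle markers (4.44). Without it the smooth muscle median was 0.44, and uneven sampling of tissue was not tested for this list. Hhip, a hedgehog-binding protein, had 32.8 ± 6.21 against 18.6 ± 5.49 CPM (0.82, SE 0.25), and Myh11 had 173 ± 59.4 against 91.4 ± 29 CPM (0.92, SE 0.31).

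Camera called 15 further lists at its preset correlation, none of which passed with an estimated correlation (adjusted p between 0.291 and 0.707). Lower were monocyte and interstitial macrophage markers (median −0.37), acute phase and antimicrobial proteins (−0.36), NK cell and cytotoxic genes (−0.48), coagulation and fibrinolysis genes (−0.43), and arachidonic acid and nitric oxide genes (−0.35). Lower too were T cell markers (−0.33), inflammasome and cell death genes (−0.28), LPS receptor and TLR signalling genes (−0.29), STAT5 and cytokine receptor target genes (−0.26), antioxidant and hypoxia genes (−0.27) and alveolar macrophage markers (−0.00205). It called higher the lists of fibroblast and matrix genes (0.24), cell cycle genes (0.26), B cell markers (0.32) and endothelial markers (0.11). In these 15 lists 0 members passed, over all genes or adjusted over the list alone. With the GC trend removed the calls of alveolar macrophage markers (median −0.03, camera adjusted p = 0.0548) and endothelial markers (0.11 before and after, 0.092) were lost, and ciliated cell markers were called higher (0.0402). Before that removal camera with an estimated correlation gave ciliated cell markers adjusted p = 0.776. Type 2 immunity and TSLP-associated genes were not called (29 of 42 members tested, median −0.00619, mean 0.08, camera adjusted p = 0.169). The remaining members of that list had too few counts to be tested. Heart muscle markers (0.94, camera adjusted p = 0.103) and 12 other lists were not called either.

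**Figure D2:**
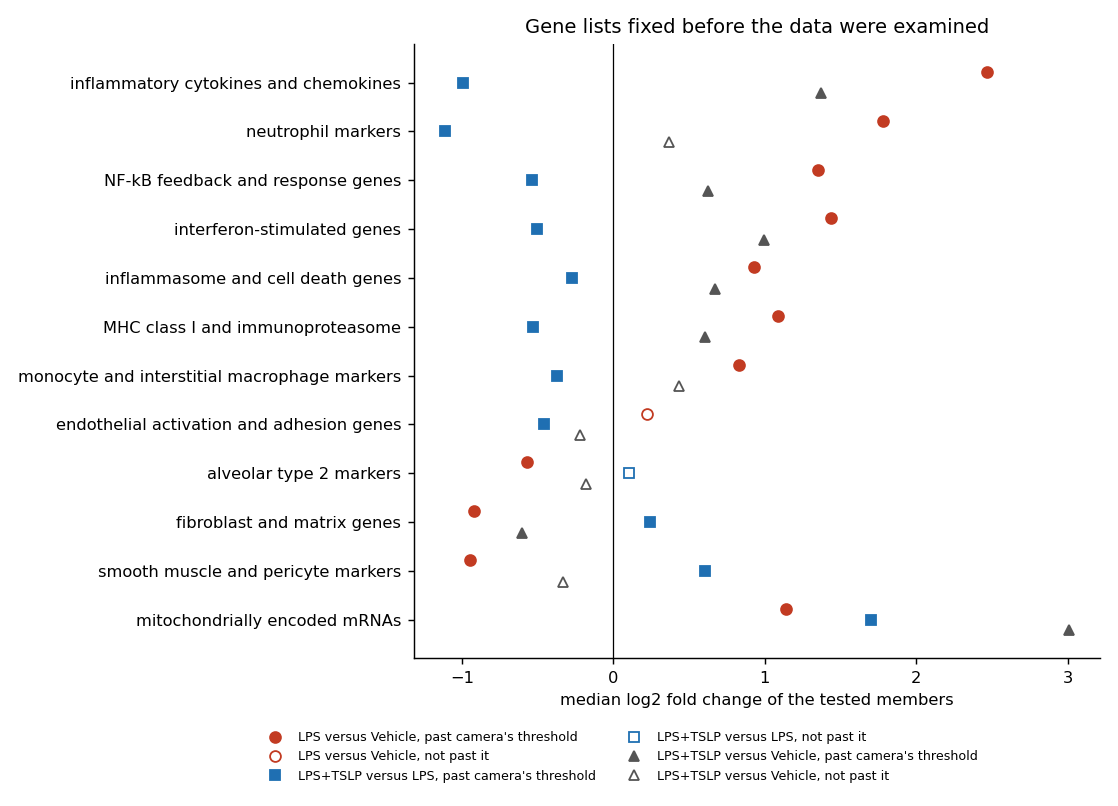
Median log2 fold change of the tested members of 12 gene lists in each comparison, with filled symbols for lists that passed camera's preset-correlation test. Inflammatory cytokines lay at 2.47 for LPS against Vehicle, −0.995 for LPS+TSLP against LPS and 1.37 for LPS+TSLP against Vehicle, and none of the calls held with an estimated correlation.

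None of the 30 anchor genes passed in this comparison, 26 of them with values below 0. Values in addition to those above were −1.23 for Il6 (SE 0.82), −1.12 for Cxcl1 (SE 0.70), −0.63 for Cxcl10 (SE 0.91), −1.34 for Ccl2 (SE 0.71), −1.69 for Csf3 (SE 0.91), and −1.58 for Saa3 (SE 0.99). They were −0.91 for Lcn2 (SE 0.75), −1.46 for S100a8 (SE 0.62), −1.60 for S100a9 (SE 0.58), −0.60 for Icam1 (SE 0.43), −1.39 for Nos2 (SE 0.55), −1.09 for Ptgs2 (SE 0.55), −0.465 for Il7r (SE 0.43) and −0.16 for Crlf2 (SE 0.22), with adjusted p from 0.59 to 0.89. Endogenous Tslp had 2.84 ± 1.39 against 2.14 ± 1.33 CPM (0.41, SE 0.63, adjusted p = 0.9), and −0.04 without LPS replicate 3.

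By edgeR quasi-likelihood 0 genes rose and 0 fell with TSLP (smallest adjusted p = 0.59), while 1388 genes (8.10%) had an unadjusted p under 0.05 and the groups did not overlap in 7.42% of genes, where chance gives 5.71%. The DESeq2 Wald test called 22 genes higher and 13 lower, among them mt-Co2 and mt-Nd4l higher and Wfdc21 and Ly6g lower, and limma-voom called 0 and 0. Without LPS replicate 3 edgeR called 1 gene lower, Gm11808 (−2.57, adjusted p = 0.00064), which is named because it was the single call. Of the 23 list calls 14 held without any 1 library, and those of alveolar macrophage (median −0.26 to 0.10 over the 10 fits), T cell, B cell, STAT5, TLR signalling, endothelial, fibroblast, antioxidant and cell cycle genes did not. Spiked changes of 4-fold in simulated counts of this design were found in 71.6% of 67 genes and changes of 2-fold in 10.4%, so that a 2-fold difference in a single gene was mostly not detectable.

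LPS+TSLP against Vehicle asked what differed from untreated lung when both agents were given. Of the inflammatory genes named first for LPS, none passed here: Cxcl2 had 3.88 (adjusted p = 0.065), Tnf 2.29 (adjusted p = 0.058) and Il1b 1.27 (adjusted p = 0.2). Cxcl2 and Tnf passed by the DESeq2 Wald test (adjusted p = 0.017 and 0.027) and by limma-voom (adjusted p = 0.037 and 0.034). With the replicate number as a block, or without Vehicle replicate 3, 2 of these inflammatory genes passed. In each of the fits without LPS+TSLP replicate 1, without LPS+TSLP replicate 4, and without both libraries that stand apart, 1 passed. Ccl4 passed and went from 6.77 ± 6.27 CPM (n = 3) to 64 ± 44.6 CPM (n = 4), a log2 fold change of 3.24 (SE 0.71, adjusted p = 0.016; 4.31 without Vehicle replicate 3 and 2.62 without LPS+TSLP replicate 3). Ifit1 went from 9.82 ± 5.84 to 139 ± 79.6 CPM (3.82, SE 0.58, adjusted p = 0.0038), and Gbp7 from 17.8 ± 8.72 to 151 ± 70.2 CPM (3.09, SE 0.43, adjusted p = 0.0026). Col14a1 fell from 79.5 ± 37.9 to 11.6 ± 5.23 CPM (−2.78, SE 0.45, adjusted p = 0.0045). The groups did not overlap in Ccl4, Ifit1, Gbp7 and Col14a1.

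Of the 32 inflammatory cytokines and chemokines 7 rose, 2 fell and 23 did not pass (14 rose and 2 fell adjusted over the list alone), with a median of 1.37. By list mean LPS+TSLP replicate 1 (4.05 log2 CPM) lay below Vehicle replicate 3 (4.12). Ccl8, a monocyte attractant, fell from 13.9 ± 5.6 to 2.66 ± 1.87 CPM (−2.38, SE 0.48, adjusted p = 0.012; −2.99 without LPS+TSLP replicate 1). NF-kB feedback and response genes had 3 risen among 25 (6 adjusted over the list alone), with a median of 0.62: Tnip3 (2.26, SE 0.38), the stress-response gene Gadd45b (1.37, SE 0.28) and Nfkbia (1.26, SE 0.29). Interferon-stimulated genes had 7 risen among 47 (7 adjusted over the list alone) and a median of 0.99. Inflammasome and cell death genes had 7 risen among 28 (10 adjusted over the list alone) and a median of 0.67, including Aim2 (1.29, SE 0.27, adjusted p = 0.013) and Casp4 (1.96, SE 0.41, adjusted p = 0.013). Fibroblast and matrix genes had 6 fallen among 32 (7 adjusted over the list alone), with a median of −0.60, including Pi16 (−1.63, SE 0.28, adjusted p = 0.0059). Camera called these 5 lists (adjusted p from 5.97e-07 to 0.000559), with adjusted p = 0.849 with an estimated correlation for each.

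All 13 mitochondrially encoded mRNAs rose (13 adjusted over the list alone), with a median of 3.01 (camera adjusted p = 5.55e-13, adjusted p = 0.849 with an estimated correlation). mt-Nd6 went from 160 ± 19.4 to 1390 ± 576 CPM (3.12, SE 0.38, adjusted p = 0.0021), and the complex I subunit mt-Nd2 from 624 ± 79.4 to 3610 ± 1500 CPM (2.53, SE 0.42, adjusted p = 0.0049). With the GC trend removed the median was 1.34 and 1 of the 13 still passed, mt-Nd4l (3.48, SE 0.60, adjusted p = 0.0059 before and 2.68, adjusted p = 0.027 after), named for that reason once its values were seen. Heart muscle markers, from a tissue rich in mitochondria, had library means of 4.44, 0.000991, 2.49 and −0.47 log2 CPM in LPS+TSLP and of 1.12, 4.41 and 0.66 in Vehicle, and the list was not called (camera adjusted p = 0.429). Camera also called MHC class I and immunoproteasome genes (2 of 19 rose; median 0.60) and glucocorticoid-responsive genes (1 of 22; 0.84) higher, and alveolar type 1 markers (0 of 26; −0.43) and fluid and ion transport genes (3 of 30 fell; −0.32) lower. Adjusted over the list alone 2, 0, 0 and 3 members of these lists passed, and each call had adjusted p = 0.849 with an estimated correlation. The other 27 lists were not called, among them type 2 immunity and TSLP-associated genes (2 rose and 2 fell of 29; camera adjusted p = 0.615) and neutrophil markers (1 rose of 32; median 0.37, camera adjusted p = 0.323). Immediate early genes were called higher once the GC trend was removed (median 0.42, camera adjusted p = 0.00072). Before that removal camera with an estimated correlation gave them adjusted p = 0.849.

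The largest fitted rises were those of Eppin, a protease inhibitor of the epididymis, Zfp991 and mt-Atp6, an ATP synthase subunit. Eppin had 0 counts in Vehicle and 72 in LPS+TSLP, 19.4-fold higher against a floor of 3 counts over the group. The lower end of its 95% counting interval was 15.4. Zfp991 had 6.77 ± 1.78 CPM in LPS+TSLP (5.03, SE 0.40), and mt-Atp6 had 384 ± 443 against 15.7 ± 5.02 CPM (4.61, SE 0.99, adjusted p = 0.014), with all of its 50-base stretches shared with other genes, and was at 3.46 without LPS+TSLP replicate 1. The largest falls were those of the complement factor and adipokine Cfd (61.8 ± 79.4 to 1.55 ± 2.05 CPM; −5.33, SE 1.5, adjusted p = 0.035) and of the fat droplet protein Plin1 (5.2 ± 4.85 to 0.179 ± 0.121 CPM; −4.81, SE 1.0, adjusted p = 0.014). Vehicle replicate 2 held 153 CPM of Cfd and 10.8 CPM of Plin1, against 17.7 and 14.1 CPM and 2.86 and 1.97 CPM in Vehicle replicates 1 and 3. Without it the values were −3.35 (adjusted p = 0.19) and −3.72 (adjusted p = 0.08), and RNA from fat in that library was not tested. Cfd was at −6.83 without LPS+TSLP replicate 1. The epithelial polarity gene Crb2 had 69 counts in Vehicle and 3 in LPS+TSLP (ratio 28.4, 95% counting interval 9.32 to 141), and its fitted log2 value of −4.64 was −3.62 without Vehicle replicate 1 and −5.57 without LPS+TSLP replicate 4. Of the 30 anchor genes 2 passed, Ptgs2 (2.45, SE 0.62, adjusted p = 0.026) and Il7r (1.55, SE 0.45, adjusted p = 0.043), picked out of that list after their values were seen.

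In all, 1511 genes rose and 917 fell, 1246 and 454 of them at least 2-fold, and 5651 genes had an unadjusted p under 0.05. The groups did not overlap in 31.7% of genes, where chance gives 5.71%. With the GC trend removed 761 genes were higher and 549 lower, of which 675 and 349 were called before, and the calls of Aim2, Casp4, Cfd, Il7r, mt-Atp6, mt-Nd2, mt-Nd6 and Ptgs2 were lost. Without 1 library the counts were 435 and 81 (Vehicle replicate 1), 404 and 117 (Vehicle replicate 2), 833 and 205 (LPS+TSLP replicate 2), 833 and 181 (LPS+TSLP replicate 3) and, for lower genes, 1478 (LPS+TSLP replicate 4). Of the 22 named calls 11 were lost without Vehicle replicate 1 and 13 without Vehicle replicate 2, those of Ccl4, Aim2, Casp4, Gadd45b, Nfkbia, Eppin, mt-Atp6, Cfd, Crb2, Ptgs2 and Il7r in both cases and those of Ccl8 and Plin1 in the second. Cfd, Crb2, Ptgs2 and Il7r were also lost without LPS+TSLP replicate 2 or 3, Nfkbia without LPS+TSLP replicate 3, Cfd and Il7r without LPS+TSLP replicate 4, and Il7r without LPS replicate 2 or 3, with values of all these genes keeping their direction. With no filter on low counts Ccl4, Cfd, mt-Atp6 and Ptgs2 were lost, by limma-voom Il7r and Ptgs2, and with the replicate number as a block Cfd. Il7r was lost too with library size as the only scaling and in a fit of LPS+TSLP and Vehicle alone. The call of MHC class I genes was lost without Vehicle replicate 1 or LPS+TSLP replicate 1 or 3 (median 0.42 to 0.79 over the 10 fits), and that of alveolar type 1 markers without LPS+TSLP replicate 1 (−0.60 to −0.15).

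Across 17139 genes, which are not independent replicates, the fold changes of both treated groups against Vehicle were correlated (Pearson r = 0.872, Spearman rho = 0.865). They share the Vehicle libraries, and 20 simulations of these libraries with no effect gave a mean r of 0.535, with a covariance of 0.121 against the observed 0.927. Each gene was drawn on its own in the simulations, so they hold no trend with GC content. Both comparisons had such a trend (Spearman rho −0.365 and −0.342). The excess over the simulations therefore does not separate a shared response to treatment from that shared trend. Of the genes that rose in LPS+TSLP against Vehicle, 1275 (84.4%) also rose in LPS against Vehicle, and of those that fell, 761 (83%) also fell. Independent calls would share 214.8 and 98.23. The simulations shared 0 and 0, but with no effect simulated few calls can arise. They therefore do not show how much overlap the shared libraries create among called genes. The fold changes of LPS against Vehicle and of LPS+TSLP against LPS, which share the LPS libraries with opposite sign, had r = −0.456 (rho = −0.52) against a simulated −0.538, and a covariance of −0.267 against a simulated −0.122. No split of 3 shared libraries leaves 2 in each part, so part of these correlations and overlaps may come from the sharing or from the GC trend.

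A response score placed each library on the axis from Vehicle to LPS, as the slope of its log2 difference from the Vehicle mean on the LPS fold change over genes called between LPS and Vehicle (3252 to 4759 genes), with each LPS library scored on the other LPS libraries. The scores were 0.914, 0.79 and 0.746 in LPS (mean 0.817 ± 0.0874, n = 3) and 0.549, 0.775, 0.833 and 0.614 in LPS+TSLP (mean 0.693 ± 0.133, n = 4). The difference of −0.12 did not exceed the spread between libraries (exact permutation p = 0.257, two-sided, 9 of 35 splits as large, smallest possible p = 0.0286).

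**Figure D3:**
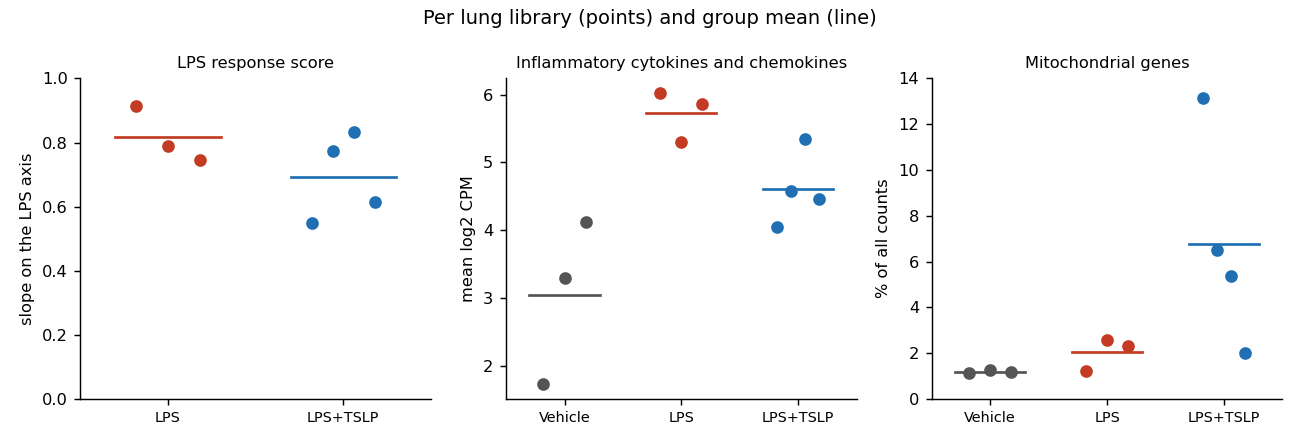
Response score, mean log2 CPM of 32 inflammatory cytokines and chemokines, and percent of counts from mitochondrial genes, with points for lung libraries and lines for group means. The scores of LPS and LPS+TSLP overlap, 3 of the 4 LPS+TSLP libraries lie below all LPS libraries in the cytokine mean, and LPS+TSLP replicate 1 has 13.1% mitochondrial counts.

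Expression varied with GC content between Vehicle and both treated groups, and no label says whether the Vehicle libraries were prepared or sequenced together with the others. In the decile of tested genes with the lowest GC content (22.1% to 42.2%) the median log2 fold change of LPS against Vehicle was 1.26, 50.7% of the 1713 genes rose and 0.409% fell. In the highest decile (57.7% to 75.5%) the median was −0.29, 5.78% rose and 18.2% fell. Across genes, fold changes had a Spearman rho with GC content of −0.365 for LPS against Vehicle, −0.342 for LPS+TSLP against Vehicle and 0.132 for LPS+TSLP against LPS. With gene length rho was −0.231, −0.205 and 0.145 in the same order, so fold changes varied with length too. The median of all tested genes was 0.0084 for LPS against Vehicle, 0.021 for LPS+TSLP against LPS and 0.027 for LPS+TSLP against Vehicle, and with library size as the only scaling it was −0.065, 0.056 and −0.01.

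**Figure D4:**
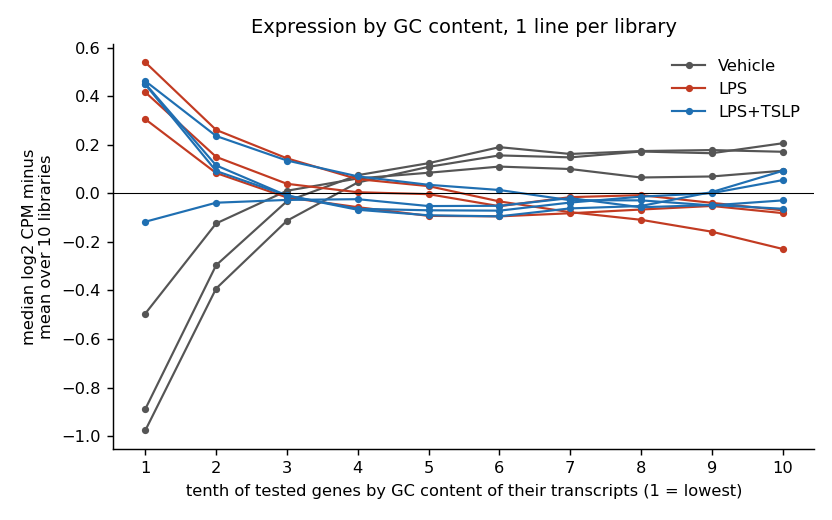
Median log2 CPM of each library minus the mean over 10 libraries, per decile of tested genes by GC content. In the lowest decile the Vehicle libraries lie between −0.976 and −0.495 and the LPS libraries between 0.305 and 0.539, with LPS+TSLP replicate 1 at −0.117 and the other 3 LPS+TSLP libraries between 0.448 and 0.462.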

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

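The tests of GC content, shared reads and gene length on AT-rich genes, and those of mitochondrial mRNAs without LPS+TSLP replicate 1 and with the GC trend removed, were chosen after the results they bear on were seen, and the others before.

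Within the 4 LPS+TSLP libraries, 12 of 108 items had a single library far from the rest, by the gap to its nearest neighbour over the group's range (Dixon's ratio at the 95% level). The items were named genes, list means, the response score and measures of the counts. Chance gives about 1 in 20 for independent items, which these are not. LPS+TSLP replicate 1 was the distant library for Gsg1l (ratio 0.959), Lcn2 (0.954), S100a8 (0.869), Icam1 (0.91), Lamp3 (0.869), Wfdc21 (0.915) and the mean of alveolar type 2 markers (0.852). LPS+TSLP replicate 3 was the distant library for Ccl4 (0.877), Tnfaip2 (0.903) and the mean of B cell markers (0.946). Plin1 had a ratio of 0.908 for LPS+TSLP replicate 2, from counts of 4, 0, 4 and 4 in LPS+TSLP replicates 1 to 4, so near the floor. For mt-Nd2 the ratio was 0.83, with LPS+TSLP replicate 4 the distant library. Groups of 3 libraries were not tested in this way.

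Xist stood out in LPS replicate 1, at 206 CPM against at most 0.218 CPM in Vehicle. In that library the Y-linked genes Ddx3y, Uty, Eif2s3y and Kdm5d had 0 CPM, whereas the lowest values in any other library were 6.03, 2.03, 10.7 and 13 CPM. Ddx3y had 7.92, 6.03 and 11.4 CPM in Vehicle, 70.1 and 89.6 CPM in LPS replicates 2 and 3, and 59.7, 94.8, 76.9 and 92.7 CPM in LPS+TSLP. No label gives the sex of the animals.

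AT-rich genes were higher in LPS than in Vehicle. After each library's mean GC trend was removed, 2685 calls (62.8%) stayed in the same direction. So did 16 of the 20 inflammatory cytokines and chemokines called higher. These calls do not rest on that mean trend. The correction leaves differences in recovery between genes of like GC content, so it cannot exclude GC-dependent recovery as their cause. Shared reads and gene length did not account for the rise of the AT-rich genes. Those without a shared stretch had a median log2 fold change of 1.08 (749 genes). The 1713 genes with the lowest GC content had 1.30 after the length trend was removed. Length trends in other genes were not judged by this test. For the AT-rich genes themselves (median 1.26), GC-dependent recovery and an effect of LPS, the biological hypothesis, cannot be told apart, because the lowest LPS library lay 0.799 log2 above the highest Vehicle library there. A separate preparation or sequencing of the Vehicle libraries, of which no label tells, would follow the groups in the same way and was not tested. Rises kept with the GC trend removed, such as those of Cxcl2 (5.10) and Ifit1 (4.22), do not rest on that trend.

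Inflammatory cytokines and chemokines had lower list means in LPS+TSLP than in LPS, by −1.12 log2 (SE 0.35, exact permutation p = 0.0857). The difference did not rest on LPS+TSLP replicate 1, without which it was −0.931 (SE 0.355), nor on LPS replicate 1, the library with Xist, without which it was −0.969 (SE 0.391). Chance was not excluded: 10 of the 35 splits of these 7 libraries gave at least as many called lists (23 for the real split, up to 25 for the others). An effect of TSLP given beforehand is a hypothesis that stays open, as do differences between the animals or in sampling, which were not tested.

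Mitochondrial mRNAs had higher list means in LPS+TSLP than in LPS, by 1.71 log2 (SE 0.587, exact permutation p = 0.0857). The means were 10.21, 9.546, 9.23 and 7.708 in LPS+TSLP replicates 1 to 4 and 6.965, 7.684 and 7.755 in LPS replicates 1 to 3. LPS+TSLP replicate 4 thus lay inside the LPS range. RNA from heart muscle is not the cause by the marker means, since the difference was 1.62 (SE 0.496) with the heart marker mean of each library as a covariate. It was 1.36 (SE 0.621) without LPS+TSLP replicate 1 and 1.76 (SE 0.693) with the GC trend removed, so neither that library alone nor the mean GC trend accounts for it. Reads shared with other annotated genes were not tested for this list. RNA quality and handling were not measured in these files and stay open beside treatment, and chance stays open too at this exact p.

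Other splits of the same libraries gave these counts. For LPS against Vehicle the real split called 4273 genes and the other 9 splits 0, with 6788 and at most 880 genes at an unadjusted p under 0.05, each 1 of 10 splits. For called lists 4 of the 10 splits gave at least the real 23, up to 25. Splits of 6 libraries are too few for a share under 0.05. For LPS+TSLP against LPS the real split called 0 genes, which all 35 of 35 splits must reach (up to 3 in another), so that count does not bear on chance. Chance was not excluded for the 1388 genes at an unadjusted p under 0.05, which 14 of 35 splits reached or passed, up to 2895. For LPS+TSLP against Vehicle only the real split reached the 2428 called genes (1 of 35 splits, highest other 1537). The same held for the 5651 genes at an unadjusted p under 0.05 (1 of 35, highest other 5154). A share of 1 in 35 is the smallest these splits allow and was not adjusted over the counts examined, so chance was made less likely but not excluded. For the 10 called lists chance was not excluded either, as 35 of 35 splits reached or passed them, up to 29. Structure of the samples and a preset correlation (0.01) below most estimated ones (up to 0.779) both stay open as reasons for the calls of other splits, and neither was tested.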

How the results depend on the processing

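The corrections for GC content and gene length together, the fits without LPS replicate 1 and LPS+TSLP replicate 1 together, camera after GC correction, the permutation test of lists, and the score with GC correction or without an LPS library were chosen after the data were seen, and the rest before. Over all alternatives 235 of the counts, scores and correlations stayed near the reported value and 57 moved, by over 1.5 times for counts or over 1 jackknife standard error for correlations. Named genes, and lists that camera had called, kept their direction and side of the threshold in 2338 and 655 cases. They lost the call in 143 and 239 cases and changed direction in 4 and 2. Named genes gained a call in 43 cases, and lists not called at first gained one in 87. The cause was not tested.

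Genes higher in LPS against Vehicle (2437) numbered 831 at an adjusted p under 0.01 and from 1012 to 2975 with 1 library left out. Genes lower (1836) numbered 415 at that threshold, 1169 at 2-fold, and 640 to 2449 with 1 library left out. For LPS+TSLP against LPS (0 and 0) the DESeq2 Wald test gave 22 and 13, and leaving out 1 library gave 0 higher and from 0 to 1 lower. Genes higher in LPS+TSLP against Vehicle (1511) numbered 2296 by DESeq2, 761 with the GC trend removed, and 848 with GC and length trends removed. They numbered 2333 with both libraries that stand apart left out, 465 at an adjusted p under 0.01, and 404 to 2015 with 1 library left out. Genes lower (917) numbered 1629, 549, 555, 1509 and 62 in the same order, 1592 with the replicate number as a block, 454 at 2-fold, and 81 to 1478 with 1 library left out. With that block the other counts were 2497 and 1996 for LPS against Vehicle, 0 and 0 for LPS+TSLP against LPS, and 1862 higher for LPS+TSLP against Vehicle.

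Lists called higher and lower were 0 and 0 in every comparison with an estimated correlation and with exact permutation of library means, where 3 against 3 libraries cannot pass. Fry, a self-contained test, gave 7 and 2 for LPS against Vehicle and 0 and 0 for the others. With 1 library left out the lists lower in LPS against Vehicle (8) ranged from 5 to 10 and those lower in LPS+TSLP against Vehicle (3) from 4 to 7. Values changed sign for Tslp in LPS against Vehicle (0.77 to −0.49 with the GC trend removed and −0.96 with GC and length trends removed) and for mt-Nd6 there (2.30 to −0.50 with both trends removed). They also changed sign for Tslp in LPS+TSLP against LPS (0.41, and −0.044 without LPS replicate 3, where the highest value with a library left out was 0.74), for mitochondrially encoded mRNAs in LPS against Vehicle (1.14 to −0.70 after GC correction) and for alveolar macrophage markers in LPS+TSLP against LPS (−0.00205 to 0.18 with both libraries that stand apart left out). The median of that list was also above 0 without LPS replicate 1 (0.0166) or LPS+TSLP replicates 1, 3 or 4 (0.1, 0.0234 and 0.00928), where camera's direction stayed down.

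The response score difference (−0.12) ranged from −0.0576 to −0.173, with exact permutation p from 0.2 to 0.771. It gave no value without LPS replicate 1, without LPS replicate 2, or without both libraries that stand apart. The LPS library left beside LPS replicate 3 was then scored on LPS replicate 3 alone. No gene was called for that axis, and the difference needs every axis. Correlations across genes ranged from −0.57 to −0.344 for LPS against Vehicle with LPS+TSLP against LPS and from 0.83 to 0.9 for LPS against Vehicle with LPS+TSLP against Vehicle.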

Other observations

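The lists and their test were fixed before their results were seen, and none was chosen after. After LPS the following lists did not pass camera. Dendritic cell markers had 5 members risen and 4 fallen of 30 (median log2 fold change 0.11), endothelial markers 2 and 8 of 32 (−0.19), alveolar macrophage markers 3 and 4 of 29. T cell markers had 2 and 0 of 30 (0.09), MHC class II and antigen presentation genes 2 and 0 of 17 (0.07). Club and secretory cell markers had 2 and 2 of 30 (−0.75), alveolar type 1 markers 0 and 1 of 26 (−0.55). Antioxidant and hypoxia genes had 4 and 2 of 32 (0.35), circadian clock genes 1 and 4 of 20 (−0.38). Immediate early genes had 3 and 1 of 26 (0.29), endothelial activation and adhesion genes 4 and 2 of 23 (0.22). Erythroid and platelet markers had 1 and 2 of 18 (0.10), and heart muscle markers 0 and 2 of 19 (−0.85). Adjusted over the list alone the members risen and fallen were 6 and 5 for dendritic cells, 2 and 9 for endothelium, and 1 and 7 for the clock.

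In LPS+TSLP against Vehicle these lists did not pass. Dendritic cell markers had 4 members risen and 3 fallen, endothelial markers 2 and 4, alveolar macrophage markers 1 and 4. Alveolar type 2 markers had 2 and 3 (median −0.18), monocyte and interstitial macrophage markers 3 and 0 (0.43). Smooth muscle and pericyte markers had 1 and 2 (−0.34), and the markers of skeletal muscle, thyroid, fat, thymus and squamous epithelium 0 and 3 (−0.96). Median, mean and test differed in sign for some lists that camera did not call. After LPS these were alveolar macrophage markers (median 0.03, mean −0.14), erythroid and platelet markers (0.10, −0.12), and type 2 immunity and TSLP-associated genes (−0.12, −0.34, direction up). In LPS+TSLP against LPS these were type 2 immunity and TSLP-associated genes (−0.00619, 0.08) and the skeletal muscle and fat list (−0.20, 0.30). In LPS+TSLP against Vehicle these were club and secretory cell markers (0.20, 0.12, direction down), ciliated cell markers (0.03, −0.08) and heart muscle markers (0.24, −0.16).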
